A study of Mus musculus with 8 samples.

How the data were processed

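The series holds 8 libraries from the mouse embryonic stem cell line A3-1, grown with serum and LIF per the labels. LIN28A is an RNA-binding protein of pluripotent cells that binds let-7 precursors and many mRNAs. CLIP-seq, in which RNA crosslinked to a protein by UV light is immunoprecipitated and sequenced, was done with 3 anti-LIN28A antibodies (35L33G, 2J3 and a polyclonal serum), 1 library each, in cells with no siRNA. Poly(A) RNA-seq covered untreated cells and cells 48 h after siRNA against luciferase (siLuc) or Lin28a (siLin28a), 1 library each. Ribosome profiling, the sequencing of ribosome-protected fragments (footprints), covered siLuc and siLin28a, 1 library each.

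The mouse genome build mm9, GSNAP and bedtools are named, without their roles, per the submitters' processing notes; versions and the counting rule are not given in the sources used here. The deposited counts are whole reads per RefSeq transcript. The CLIP table holds exon, coding and 3′ UTR counts for 7820 transcripts (87 non-coding), the poly(A) table exon counts for 16456 transcripts, and the footprint table footprint and poly(A) counts for 7936 transcripts, each with at least 80 poly(A) counts in each library. The authors' deposited exon log2 ratios of CLIP over poly(A) equalled log2 of the ratio of counts plus 1, without a depth factor. These exon ratios were listed at 0 for 135 to 161 transcripts per antibody. The authors' deposited log2 change of ribosome density equalled the count ratio plus a constant of 0.63. The p-value and FDR columns deposited by the authors and 8 columns of per-sample values were not used. Columns labelled as 5′ UTR equalled the exon counts in 97.5% of transcripts and were not analysed. Symbols and transcript identifiers were used as in the files; 7744 of 7820, 16199 of 16456 and 7863 of 7936 identifiers were found in the RefSeq gene table supplied for mouse.

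Poly(A) reads were tallied differently in different tables. The poly(A) column of the CLIP table names no condition; across transcripts its rank correlation was 0.986 with the untreated counts and 0.959 with siLuc. The untreated counts of the poly(A) table were taken as the CLIP input. For 92 transcripts the tallies differed over 2-fold from the median ratio, 83 of them higher in the CLIP table; these, like histone genes with near-identical copies, are treated as uncertain. The footprint table's poly(A) counts were used for ribosome density, within that table; the alternative without disagreeing tallies there kept 7298 of 7799 transcripts, leaving out those 92 and any tallied over 2-fold higher in the footprint table than the median ratio, not those tallied lower.

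CLIP enrichment was tested with edgeR 4.0.16 (R 4.3.3), quasi-likelihood test, TMM factors and filterByExpr, CLIP (3 libraries) against poly(A) untreated (1 library), with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread came from the 3 antibodies alone, whose libraries are not stated to come from separate cultures, and the single input is assumed to vary like them; p-values therefore measure the spread between these libraries, which may be technical. Log2 enrichment per antibody used a pseudocount of 0.5 counts, and values are means ± SD over the 3 antibodies. Gene lists of at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists; the joined classes, outside that family, have an unadjusted p. DESeq2 1.42.0 was run as an alternative. On simulated counts for 7820 transcripts the gene test recovered 14% of transcripts changed 1.5-fold and 66% of those changed 2-fold. None had the wrong sign, and 5.88% of its calls were unchanged transcripts. Camera called the shifted list (adjusted p = 1.5e-32, edgeR counts) and 0 of 20 unchanged lists. The simulated input was drawn with the same dispersion as the CLIP libraries, and most transcripts were left unchanged. The simulation therefore cannot show the error rate in the real data.

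The siRNA comparisons have 1 library per condition and no replicate check, so no p-value is given. Changes are log2 ratios of CPM (counts scaled to the library total) with a pseudocount of 0.5 counts and 95% intervals that cover counting error only: exact Poisson for levels and exact Clopper-Pearson for ratios of Lin28a, Lin28b and CLIP transcripts with few counts, and a normal approximation on the log scale elsewhere. Ribosome density change is the footprint change minus the mRNA change of the footprint table, for 7799 of 7936 transcripts with 50 counts or more in each assay, centred on the median transcript; by total counts that median lay at −0.22. The spread of changes is the scaled median absolute deviation over transcripts. List medians are given as percentiles among 10000 random lists of the same size matched on poly(A) count in 10 bins, as a description of these libraries. On simulated counts for 7795 transcripts a list shifted by 0.3 was placed at percentile 100. Of the unchanged lists, 0 of 20 lay outside 2.5 to 97.5. The simulated transcripts differed by counting error only (median SE 0.17 in the real data), whereas the real density spread was 0.62. The simulation therefore cannot show what shift would be found in the real data. A floor of 3 counts was used for ratios against 0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

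Lists, tests and the rule for naming genes were fixed before the data were examined. The rule names Lin28a; in CLIP the 10 highest and 8 lowest mean enrichments among transcripts with an adjusted p under the threshold, the same sign in all 3 libraries and a mean of 100 counts; in the siRNA comparisons the 8 highest and 8 lowest changes among transcripts with 200 counts in sum, for mRNA with the same sign against untreated; and in each list up to 4 members with the highest untreated count. Clone names and genes sharing reads with copies were skipped. Of the genes the rule names, 1 is not reported here. A further naming rule, highest CLIP enrichment with 200 untreated counts or more and agreeing tallies, was added after seeing the data. Alternatives covered scaling, filters, input library, test, each antibody left out, mRNA reference and pseudocount; those added after seeing the data are named in the closing section. A class of proteins with computed hydrophobic segments was planned and not run, since no coding sequences were used here.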

Results

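The data cover LIN28A-bound RNA (3 CLIP libraries, 1 per antibody), poly(A) RNA (untreated, siLuc and siLin28a, 1 library each) and ribosome footprints (siLuc and siLin28a, 1 library each) of A3-1 mouse embryonic stem cells. CLIP libraries held 7698479 (35L33G), 7849235 (2J3) and 8027670 (polyclonal) exon counts. Poly(A) libraries held 9264777 (untreated), 7475174 (siLuc) and 9605641 (siLin28a) counts. Footprint libraries held 7570209 (siLuc) and 5980673 (siLin28a) counts.

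Lin28a mRNA (NM_145833; mm9 chromosome 4, 133559245 to 133574731) was read first as the check of the siRNA. Its poly(A) level in CPM, counts scaled to the library total, was 465 in untreated cells (95% counting interval 451 to 479), 354 with siLuc (341 to 368) and 118 with siLin28a (111 to 125). With siLin28a, 33.4% of the siLuc level was left (31.1 to 35.8) and 25.4% of the untreated level (23.8 to 27.2). Lin28a footprints stood at 119 CPM with siLuc (111 to 127) and 30.4 with siLin28a (26.2 to 35.2), which left 25.7% (21.8 to 30.1). The poly(A) counts tallied in the footprint table were fewer for Lin28a, 398 with siLuc and 223 with siLin28a, or 55.4 and 24.2 CPM. In that tally, used for ribosome density, the log2 change was −1.19, smaller in size than −1.58 in the poly(A) table. The paralog Lin28b stood at 65.5 CPM untreated, 51.8 with siLuc and 33.9 with siLin28a. Lin28a in the CLIP libraries was at 375, 432 and 405 CPM. Intervals cover counting error only, and no siRNA condition had a replicate.

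The first comparison asks whether the 3 antibodies recovered the same RNAs. Across 7775 transcripts with at least 10 counts in every library, the rank correlation of log2 enrichment over untreated poly(A) RNA was 0.967 for 35L33G with 2J3. It was 0.965 for 35L33G with the polyclonal serum and 0.966 for 2J3 with the polyclonal serum. The shared untreated library enters all 3 values; for the CLIP counts themselves the correlations were 0.980, 0.978 and 0.978. Enrichment had the same sign in all 3 libraries for 89.7% of transcripts, and the median SD over antibodies was 0.15. These correlations are across transcripts, which are not independent replicates.

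The second comparison asks which RNAs were over- or under-represented in LIN28A CLIP relative to untreated poly(A) RNA. Most of the 10 transcripts with the highest enrichment were replication-dependent histone mRNAs, which are described with the histones. With genes that share reads with copies skipped, most of the highest were small RNAs. Mirlet7f-1, a let-7 precursor and so a known kind of LIN28A partner, had 493, 345 and 414 CLIP counts against 3 poly(A) counts, a ratio of 204 (counting interval 69.5 to 988). Mirlet7g had a log2 enrichment of 5.60 ± 0.60 (SD, n = 3). The minor spliceosome RNAs Rnu11 and Rnu12 had ratios of 2105 (378 to 83152) and 268 (47.9 to 10594) against 1 poly(A) count each. These ratios pool the 3 antibodies, so their intervals leave out the spread between antibodies. The SD of log2 enrichment over antibodies was 1.17 for Rnu11 and 0.78 for Rnu12. The vault RNA Vaultrc5 had a ratio of 373 (127 to 1808) and Mir677 of 80.5 (27.4 to 392), against 3 poly(A) counts each. Their SDs over antibodies were 0.17 and 1.10. Mir1944 had a log2 enrichment of 5.17 ± 1.22, the snoRNAs Snord15a and Snord42a 5.16 ± 1.19 and 5.07 ± 0.48, and Hspb11 5.18 ± 0.22 (SD, n = 3).

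Among transcripts with at least 200 untreated counts, a rule chosen after the values were seen, Pgrmc1 was highest at 4.54 ± 0.02 (NM_016783, mm9 chromosome X, 34138220 to 34146074; SD, n = 3; adjusted p = 7.6e-20, edgeR quasi-likelihood test). Pgrmc1 is a membrane-anchored heme-binding protein. Ktn1, an ER membrane protein, followed at 3.38 ± 0.04 and the adhesion protein gene Pvrl3 at 3.32 ± 0.08. The ER thioredoxins Tmx1 and Tmx3 were at 3.21 ± 0.03 and 3.13 ± 0.12, and the zinc transporter gene Slc30a1 at 3.18 ± 0.06. The ER chaperone gene Dnajb11 was at 3.15 ± 0.16, Marcks at 3.14 ± 0.20, Ergic2 at 3.13 ± 0.10 and Lnpep at 3.13 ± 0.09.

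Lowest was Utf1, a transcription factor of embryonic stem cells, at −4.63 ± 0.45 (NM_009482, mm9 chromosome 7, 147129755 to 147131011; adjusted p = 5.0e-15, edgeR). Mtap1s was at −3.89 ± 0.40, Zbtb45 at −3.75 ± 0.24 and Ccdc61 at −3.73 ± 1.11. The non-coding Mirg was at −3.56 ± 0.42, Dus3l at −3.48 ± 0.22, Echdc2 at −3.38 ± 0.30 and Arhgap8 at −3.35 ± 0.28. Lin28a mRNA itself was at 0.11 ± 0.11 (adjusted p = 0.316, edgeR) and at −0.26 with total counts. Lin28b was at 1.77 ± 0.06 (adjusted p = 1.2e-09, edgeR; n = 3).

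In all, 2702 of 7820 transcripts were enriched and 2604 depleted by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1688 and 1631 of them by at least 2-fold. Scaling by total counts moved the median transcript to −0.38 and gave 1984 enriched and 3605 depleted. Directions below are relative to the TMM-scaled median. The series holds no control CLIP library. The calls therefore do not separate LIN28A binding from other differences between CLIP and poly(A) RNA-seq.

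Transcripts of the preset lists meant for proteins made at the endoplasmic reticulum (ER) were mostly enriched. Not every member is made there. The translocation list includes cytosolic signal recognition particle subunits (Srp genes), and the TMEM list is a name pattern. Of 27 ER chaperones and folding enzymes 26 were enriched, 0 depleted and 1 not called, the same adjusted over the list alone, with a median of 1.87. P4hb was at 1.605 ± 0.07, Canx at 3.06 ± 0.01, Hsp90b1 at 2.75 ± 0.09 and Hspa5 at 1.66 ± 0.02 (SD, n = 3). Of 45 plasma membrane receptors and adhesion proteins 39 were enriched and 0 depleted, the same adjusted over the list alone (median 1.29). Among them were Cdh1 at 1.99 ± 0.05, Tfrc at 1.71 ± 0.03 and Epcam at 1.27 ± 0.03. Of 21 members of the ER translocation machinery 16 were enriched and 2 depleted (17 and 2 adjusted over the list alone; median 1.31). Ssr2 was at 2.81 ± 0.04 and Sec61a1 at 0.61 ± 0.03. Of 31 lysosomal proteins 25 were enriched and 1 depleted (26 and 1 adjusted over the list alone; median 1.20). Lamp1 was at 1.41 ± 0.04 and Ctsd, not called, at 0.23 ± 0.10. Of 31 N-glycosylation and GPI anchor enzymes 20 were enriched and 4 depleted, the same adjusted over the list alone (median 0.97). Stt3a was at 2.25 ± 0.05 and Rpn2 at 1.00 ± 0.02.

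Of 104 solute carriers outside the mitochondrial SLC25 family 64 were enriched and 11 depleted, the same adjusted over the list alone (median 0.89). Slc38a2 was at 2.03 ± 0.04 and Slc2a1, not called, at 0.02 ± 0.17. Of 87 TMEM proteins 52 were enriched and 11 depleted (53 and 11 adjusted over the list alone; median 0.88). Tmem2 was at 1.95 ± 0.13 and Tmem131 at 1.78 ± 0.02. Tmem183a, not called, was at −0.01 ± 0.11, and Tmem55b, whose tallies disagree, at −3.36 ± 0.36. Of 26 extracellular matrix and secreted proteins 19 were enriched and 3 depleted, the same adjusted over the list alone (median 0.86). Fn1 was at 0.98 ± 0.02 and Lamc1 at 1.40 ± 0.03. These 8 lists and the histones passed camera at the preset correlation, with adjusted p on edgeR counts from 2.7e-21 (ER chaperones) to 0.000928 (TMEM proteins). None passed with an estimated correlation. By camera with an estimated correlation, adjusted p was 0.182 for N-glycosylation, 0.263 for the extracellular matrix and 0.144 for each of the others. The estimates were below the preset 0.01 for the translocation machinery (−0.047), plasma membrane receptors (0.0004), solute carriers (0.0071), TMEM proteins (−0.0067) and N-glycosylation (0.0085). For those lists a larger correlation was not what raised p. The estimates were above it for ER chaperones (0.019), lysosomal proteins (0.017), the extracellular matrix (0.104) and histones (0.131).

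Histones had a median of 6.20, also with the member at 0 put at its bound, with 29 of 35 enriched and 4 depleted, the same adjusted over the list alone. All 26 measured Hist genes were enriched. Their mRNAs mostly end without a poly(A) tail, and they share reads with near-identical copies, so their values are uncertain. Hist1h2ad had 0 counts in the untreated library and was at least 943-fold higher in CLIP against a floor of 3 counts in that library. The 9 variant histone genes ranged from −2.13 to 1.94, with H2afv at 1.94 ± 0.12 and H2afx at −1.03 ± 0.13 (SD, n = 3).

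The replication, pluripotency and proteasome lists were lower at the preset correlation only. Of 34 replication and cell cycle genes 19 were depleted and 3 enriched, the same adjusted over the list alone (median −0.56; adjusted p = 0.000297, camera on edgeR counts, and adjusted p = 0.144 with an estimated correlation). Mcm3 was at −1.62 ± 0.10, Mcm5 at −1.36 ± 0.05 and Top2a, not called, at 0.10 ± 0.05. Of 28 pluripotency factors 16 were depleted and 8 enriched, the same adjusted over the list alone (median −0.65; adjusted p = 0.0056, camera on edgeR counts, and adjusted p = 0.2 with an estimated correlation). Pou5f1 was at −1.45 ± 0.08 and Esrrb at −1.30 ± 0.01, against Tet1 at 1.76 ± 0.02 and Sox2 at 0.76 ± 0.07. Of 35 proteasome subunits 14 were depleted and 6 enriched, the same adjusted over the list alone (median −0.26; adjusted p = 0.0321, camera on edgeR counts, and adjusted p = 0.263 with an estimated correlation). Psmd3 was at −1.56 ± 0.03 and Psmb4 at −0.37 ± 0.08.

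The remaining lists did not pass camera in the main setting. With total counts, translation factors passed as lower at the preset correlation (adjusted p = 0.0451, camera on edgeR counts). With an estimated correlation they did not (adjusted p = 0.217, camera). Mitochondrial SLC25 carriers had a median of −0.48 (6 enriched, 12 depleted of 26), splicing factors −0.20 (17 and 22 of 57) and chaperonin and cytosolic chaperones −0.22 (6 and 10 of 18). Translation factors were at −0.09 (20 and 22 of 60), mitochondrial ribosomal proteins at −0.22 (18 and 18 of 68; 17 and 18 adjusted over the list alone) and interferon response genes at −0.06 (2 and 2 of 6). The unfolded protein and integrated stress response was at 0.57 (7 and 4 of 14). Golgi and vesicle coats were at 0.22 (13 and 11 of 31), which turned to −0.14 with total counts. Likewise let-7 targets were at 0.12 (11 and 10 of 29) and −0.25 with total counts, and silencing proteins at 0.17 (6 and 4 of 15) and −0.19 with total counts. For oxidative phosphorylation subunits the median was −0.08, the mean 0.07 and camera's direction up (28 and 26 of 69; 29 and 26 adjusted over the list alone). For p53 targets the median was −0.11, the mean 0.11 and camera's direction up (4 and 3 of 10). Cytosolic ribosomal proteins, which share reads with pseudogenes, had 26 enriched and 18 depleted of 55 with a median of 0.33, and −0.03 with total counts. With the CLIP table's own poly(A) column as input the calls were 12 and 30, so their direction is uncertain. Of the lineage markers 2 were measured (Otx2 at 0.34 ± 0.40, Tubb3 at −1.84 ± 0.40) and of the fibroblast markers 4 (2 enriched, 1 depleted), with Vim at −0.80 ± 0.05, too few to test.

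**Figure D1:**
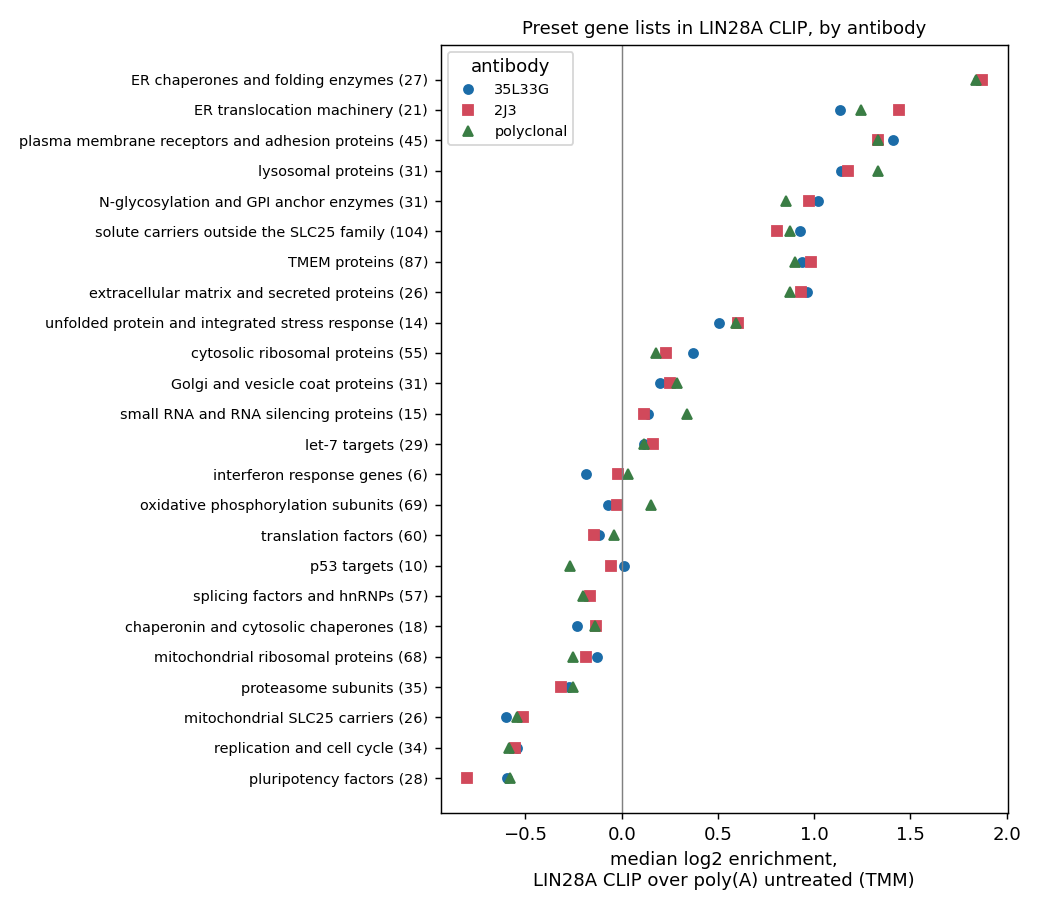
Median log2 enrichment in LIN28A CLIP over untreated poly(A) RNA (x axis) for each preset list of 5 or more measured members except histones (y axis, members in parentheses), with 1 symbol per antibody. ER chaperones lie at 1.84 to 1.87, and pluripotency factors at −0.81 to −0.58.

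The third comparison asks how mRNA levels differed after Lin28a siRNA, with 1 library per condition. Apobec2 had the highest siLin28a to siLuc log2 ratio, 2.53 (95% counting interval 2.08 to 2.98), with 34.3 CPM against 5.89 with siLuc and 5.50 untreated. Islr2 was at 2.45 (1.95 to 2.95), the cholesterol transporter gene Abca1 at 2.40 (2.00 to 2.80), Fbp2 at 2.35 (1.78 to 2.92) and Spats2l at 2.26 (1.73 to 2.80). Cdh4 was at 2.06 (1.59 to 2.53) and the calcium pump gene Atp2a3 at 2.05 (1.82 to 2.29). Lowest were Chac1, a glutathione-degrading enzyme of the stress response, at −2.43 (−2.84 to −2.01), Slfn9 at −2.37 (−2.80 to −1.93) and Trib3 at −1.67 (−1.90 to −1.43). Arrdc4 was at −1.66 (−1.89 to −1.44), Lin28a at −1.58, Spn at −1.53 (−1.93 to −1.14), Txnip at −1.52 (−1.63 to −1.41) and Lama3 at −1.40 (−1.63 to −1.16). Against untreated cells Chac1 was at −0.62, Trib3 at −0.53 and Txnip at −0.68; siLuc itself was at 1.802, 1.13 and 0.85 over untreated for these genes.

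Of 8859 transcripts with 200 counts or more, 146 were at least 2-fold higher and 39 at least 2-fold lower than with siLuc, and 83 and 12 differed this much from both siLuc and untreated. The siLuc library differed from untreated by 2-fold for 37 and 23 transcripts. The spread of log2 ratios was 0.36 for siLin28a against siLuc and 0.31 for siLuc against untreated. Pluripotency factors had a median of 0.26 against siLuc (percentile 99.98 of matched lists) and 0.10 against untreated (94.7). Extracellular matrix genes were at 0.26 (99.96) and 0.28 (100), plasma membrane receptors at 0.22 (99.99) and 0.11 (97.9), and oxidative phosphorylation subunits at 0.16 (99.94) and 0.08 (97.2). Proteasome subunits were at −0.22 (percentile 0.07) and −0.16 (0.49), cytosolic chaperones at −0.29 (0.13) and −0.16 (2.45), and replication and cell cycle genes at −0.15 (2.12) and −0.18 (0.07). Splicing factors were at −0.13 (1.02) and −0.07 (8.54), and interferon response genes at −0.39 (0.78) and −0.17 (12.5). Outside the range against untreated but not against siLuc were ER chaperones at 0.26 (99.95) and p53 targets at 0.38 (99.9). So were solute carriers outside SLC25 at −0.16 (0), TMEM proteins at −0.12 (0.09) and translation factors at −0.13 (0.35). For siLuc over untreated, with no Lin28a siRNA, p53 targets were already at 0.32 (99.94) and ER chaperones at 0.14 (98.2). Solute carriers outside SLC25 were at −0.19 (0) there and TMEM proteins at −0.10 (1.33). Translation factors were within the range there, at −0.03 (19.6). The unfolded protein and integrated stress response list was at −0.47 against siLuc (percentile 0) and 0.15 against untreated (92.3), on opposite sides.

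The fourth comparison concerns ribosome footprints. The collagen gene Col4a1 was highest with siLin28a at 2.64 (2.53 to 2.75), followed by Atp2a3 at 2.61 (2.27 to 2.95), the water channel gene Aqp3 at 2.29 (2.17 to 2.40) and Grin1 at 2.17 (1.86 to 2.47). A2m was at 2.14 (2.06 to 2.22), Col11a1 at 2.09 (1.94 to 2.24), Adamts9 at 2.07 (1.73 to 2.41) and Crtac1 at 1.97 (1.78 to 2.16). Lowest were the replication helicase gene Mcm5 at −2.11 (−2.25 to −1.98), Bms1 at −2.02 (−2.38 to −1.66), Lin28a at −1.96 and the tRNA synthetase gene Nars at −1.95 (−2.12 to −1.78). Unc45a was at −1.92 (−2.36 to −1.47), Dnmt3l at −1.91 (−2.07 to −1.76), Ppig at −1.87 (−2.38 to −1.36) and Rbm28 at −1.80 (−2.12 to −1.48). Of 6323 transcripts 243 were at least 2-fold higher and 578 lower by total counts, where the median transcript lay at −0.21. With TMM they were 547 and 245, so the balance of the counts depends on the scaling.

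The fifth comparison sets the footprint change against the mRNA change, as ribosome density, relative to the median transcript. By total counts the median transcript lay at −0.22. Tmem70 was highest at 1.89 (1.43 to 2.35), followed by Tmtc4 at 1.78 (1.26 to 2.31), Rnf121 at 1.73 (1.34 to 2.12) and the lysosomal Ifi30 at 1.73 (1.43 to 2.03). Col11a1 was at 1.72 (1.32 to 2.13), the glycosylation enzyme gene Alg5 at 1.72 (1.28 to 2.16), the amino acid transporter gene Slc1a4 at 1.70 (1.35 to 2.05) and the endosomal Eea1 at 1.69 (1.28 to 2.10). Lowest were Rhpn2 at −1.83 (−2.40 to −1.25), Anxa6 at −1.80 (−2.03 to −1.58), Mpp1 at −1.80 (−2.21 to −1.38) and Unc45a at −1.68 (−2.15 to −1.21). Dpysl3 was at −1.63 (−2.09 to −1.17), the decay factor gene Upf1 at −1.60 (−1.80 to −1.39), Ankmy2 at −1.54 (−1.99 to −1.08) and Cand2 at −1.52 (−1.996 to −1.03). Of 6285 transcripts with 200 counts per assay, 345 were at least 2-fold above and 213 at least 2-fold below the median transcript. With untreated cells as the mRNA reference they were 560 and 244. That alternative, here and below, takes both mRNA libraries from the poly(A) table. It thus changes the tally as well as the reference, and footprints stay against siLuc.

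The preset ER lists lay above the matched random lists. Lysosomal proteins had a median of 0.95 (percentile 100; all 31 above the median transcript), with Lamp1 at 1.13 (1.03 to 1.23) and Ctsd at 0.92 (0.81 to 1.03). Solute carriers outside SLC25 were at 0.87 (87 of 88 above) and plasma membrane receptors at 0.85 (45 of 45), with Cdh1 at 0.97 (0.89 to 1.06). Extracellular matrix and secreted proteins were at 0.83 (27 of 27), with Fn1 at 0.72 (0.70 to 0.75), and TMEM proteins at 0.81 (64 of 67). N-glycosylation enzymes were at 0.78 (29 of 29), with Rpn1 at 0.76 (0.67 to 0.86). ER chaperones were at 0.72 (25 of 25), with Hsp90b1 at 1.13 (1.08 to 1.18) and Hspa5 at 0.49 (0.42 to 0.55). The translocation machinery was at 0.67 (19 of 21, percentile 99.99), with Ssr3 at 0.95 (0.76 to 1.14) and Sec61a1 at 0.42 (0.28 to 0.55). Oxidative phosphorylation subunits were at 0.42 (percentile 100) and the unfolded protein and integrated stress response at 0.38 (98.7). The latter was at 0.18 (88.2) with 200 counts per assay and 0.18 (87.3) with untreated cells as the mRNA reference. Cytosolic ribosomal proteins were at 0.07 (99.99), a median that would be negative by total counts, but at percentile 74.1 with the 8 members whose poly(A) tallies agree.

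Below the random lists lay cytosolic chaperones at −0.59 (percentile 1.90) and splicing factors at −0.40 (0.99). Among the chaperones Hsp90ab1 was at −0.86 (−0.88 to −0.83) and Cct2 at −0.46 (−0.53 to −0.38). Among splicing factors Sf3b1 was at −0.90 (−1.004 to −0.79) and Hnrnpab at 0.004 (−0.06 to 0.06). Replication and cell cycle genes were at −0.45 (1.61), with Mcm5 at −1.30 (−1.45 to −1.16) and Mcm6 at −0.39 (−0.47 to −0.30). Pluripotency factors were at −0.45 (1.55), with Sox2 at −0.53 (−0.63 to −0.43), but at 0.040 (93.2) by footprints alone. Esrrb was at −0.37 (−0.47 to −0.27), Pou5f1 at 3.4e-05 (−0.06 to 0.06) and Tet1 at 0.14 (−0.03 to 0.31). With untreated cells as the mRNA reference pluripotency factors were at −0.08 (73.9) and replication and cell cycle genes at −0.40 (4.43). Without transcripts whose tallies disagree the percentiles were 3.63 for cytosolic chaperones, 5.29 for splicing factors, 2.55 for pluripotency factors and 0.98 for let-7 targets. Within the random range were let-7 targets at −0.28 (2.52), mitochondrial SLC25 carriers at 0.26 (93.1), proteasome subunits at −0.12 (73.3), translation factors at −0.18 (36.5), silencing proteins at −0.22 (28.4) and interferon response genes at −0.22 (14.4). The interferon list lay below the range with 200 counts per assay, which left 5 members (−0.52; 2.27), with untreated cells as the mRNA reference (−0.53; 1.00) and by footprints alone (−0.63; 0.22). Also within the range were mitochondrial ribosomal proteins at 0.13 (94.3), Golgi and vesicle coats at 0.07 (92.3), histones at 0.17 (83.2) and p53 targets at 0.11 (63.4), whose medians would be negative by total counts. By footprints alone Golgi and vesicle coats were above the range at 0.24 (99.52), as were SLC25 carriers with untreated cells as the mRNA reference at 0.37 (97.62). Without disagreeing tallies histones were at −0.21 (18.7) and Golgi and vesicle coats at −0.05 (72.0), and with untreated cells as the mRNA reference p53 targets were at −0.22 (14.6), each still within the range.

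**Figure D2:**
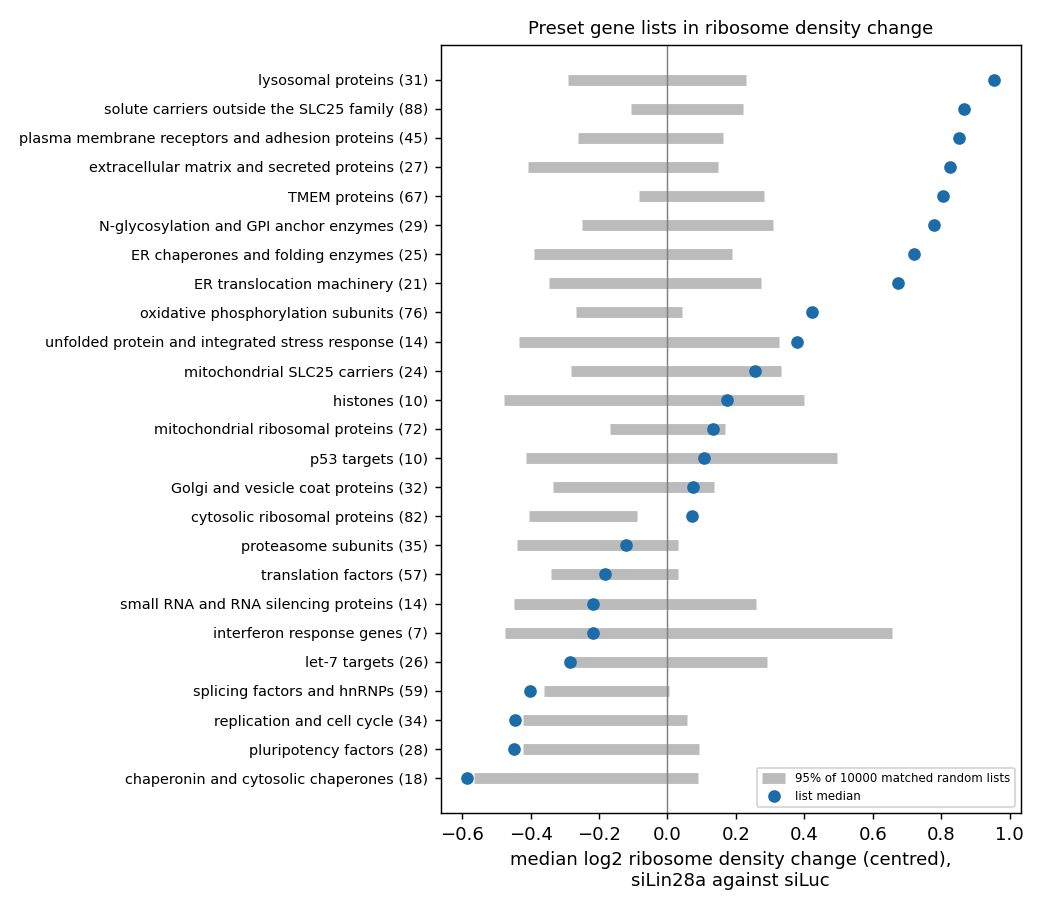
Median log2 ribosome density change, siLin28a against siLuc, centred on the median transcript (x axis), for each preset list (y axis, members in parentheses); points are list medians and grey bars the central 95% of 10000 random lists matched on poly(A) count. The 8 preset ER lists lie between 0.67 and 0.95, above their bars.

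The ER lists joined (the ER-targeted class) were compared with the lists of proteins made on free ribosomes joined. In CLIP, 261 of 372 ER class members were enriched and 32 depleted (263 and 32 adjusted over the list alone), with medians of 1.13, 1.11 and 1.11 by antibody. The camera p on edgeR counts was 1.3e-18 at the preset correlation and 0.00614 with an estimated correlation. With an estimated correlation it was 0.0594 without 35L33G, 0.0557 without 2J3 and 0.0485 without the polyclonal serum. The free-ribosome class had 130 enriched and 161 depleted of 422 (131 and 162 adjusted over the list alone) and a median of −0.19. Its camera p on edgeR counts was 0.125 at the preset correlation and 0.0758 with an estimated correlation. At the preset correlation it was 0.0269 with total counts, 0.000341 with the CLIP table's poly(A) column and 0.0316 without disagreeing tallies. With an estimated correlation these were 0.0833, 0.0153 and 0.0433. In ribosome density the ER class had a median of 0.85 (quartiles 0.68 and 1.05), with 327 of 333 above the median transcript. The free-ribosome class had a median of 0.02 (quartiles −0.31 and 0.34; 457 transcripts), a difference of 0.83 with a counting SD of 0.0137. The matched random lists of the free-ribosome class lay between −0.21 and −0.08.

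The last comparison asks whether transcripts more enriched in CLIP differed more in ribosome density. Across 7111 transcripts the rank correlation was 0.484 and Pearson's r 0.494, and by antibody the rank correlation was 0.485, 0.479 and 0.473. The median density change was −0.39 in the lowest decile of enrichment, where 22.3% of transcripts lay above the median transcript, and 0.74 in the highest, where 89.3% did. Outside the ER class the rank correlation was 0.455 (6791 transcripts), within it 0.321 (320 transcripts), and within the free-ribosome class 0.266 (416 transcripts). In each of the 4 deciles with 20 or more class members the ER class lay above the other transcripts, by 0.27 to 0.77. The footprint change alone had a rank correlation of 0.284 with CLIP enrichment and the mRNA change alone −0.295. Density with untreated cells in the mRNA change had 0.276. There the untreated library enters both sides with opposite signs, so noise in it pulls the correlation down. The siLuc to untreated mRNA change, with no Lin28a siRNA, had a rank correlation of 0.260 with CLIP over siLin28a poly(A) RNA.

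**Figure D3:**
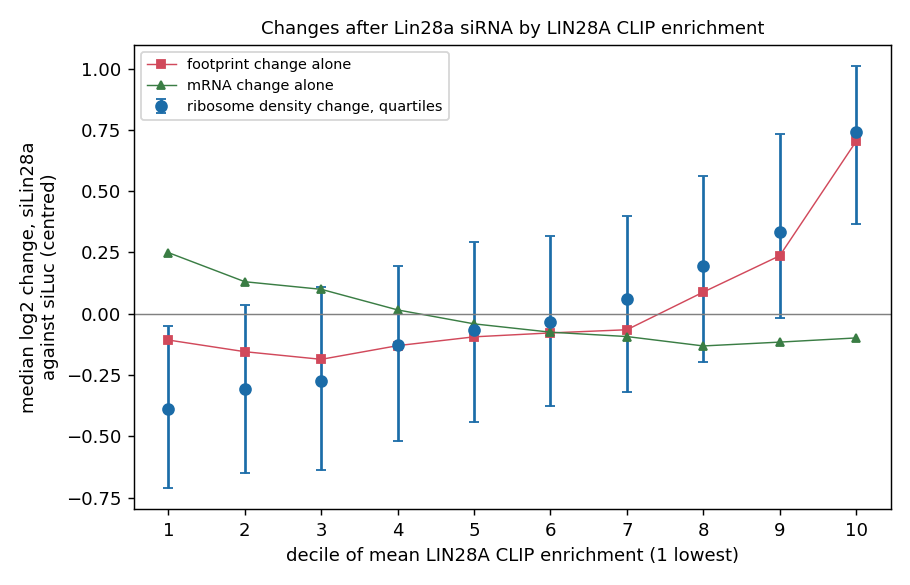
Median log2 change after Lin28a siRNA (y axis, centred) by decile of mean LIN28A CLIP enrichment (x axis, 1 lowest): ribosome density with quartile bars, and the footprint and mRNA changes alone. Density change goes from −0.39 to 0.74 and the mRNA change from 0.25 to −0.10. The footprint change is −0.11 in decile 1, −0.07 in decile 7 and 0.70 in decile 10.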

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

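Of the alternatives below, those using the CLIP table's poly(A) column, leaving out transcripts with disagreeing tallies, leaving out histones and non-coding RNAs, or rescaling Lin28a footprints were chosen after seeing the data, as was the untreated mRNA reference in the relation. The antibody agreement and the counts of enriched and depleted transcripts stayed within 1.5 times their reported values under each alternative (1984 to 2826 enriched, 2444 to 3605 depleted); leaving out each antibody gave 2581 to 2677 and 2474 to 2589. The filter alternative was void, since it removed 0 transcripts. Of the lists in CLIP, 9 were higher and 3 lower without any 1 antibody; with an estimated correlation 0 and 0 were called, and with the CLIP table's poly(A) column 6 were lower. With that column the median of cytosolic ribosomal proteins turned negative (−0.51), and camera's direction for oxidative phosphorylation, not called either way, turned from up to down (median −0.13, negative in both). Cytosolic ribosomal proteins were also at −0.10 without transcripts whose tallies disagree; shared pseudogene reads were not separated. The ER class median in CLIP was 1.085 to 1.13 without each antibody, though its camera p with an estimated correlation passed the threshold without the polyclonal serum and not without 35L33G or 2J3, with fewer libraries in each. Lin28a footprints were at −1.73 with TMM. Footprint counts under TMM were 547 higher and 245 lower, by the shift of the median transcript. With untreated cells as mRNA reference 560 transcripts were at least 2-fold higher in density. Without disagreeing tallies 2 lists lay below the random lists. The relation was 0.479 to 0.486 without each antibody, 0.503 with 200 counts per assay and 0.455 without the ER class. It was 0.284 for footprints alone and −0.295 for mRNA alone. With untreated cells in the mRNA change it was 0.276, which puts the untreated library on both sides with opposite signs and changes the tally. The effect of that sharing was not separated from the change of tally or from the difference between the siLuc and untreated libraries. By footprints alone pluripotency factors were at 0.040 in place of −0.45. Where no reason is given, the cause was not tested. The alternatives for computed hydrophobic segments were not run. No paired analysis was possible because the siRNA groups have 1 library each and the antibodies share no number with them. Input counts of 1 to 24 limit the precision of the ratios of the small RNAs named. So does the spread between antibodies, with a log2 SD of 1.17 for Rnu11 and 1.10 for Mir677.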

Other observations

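All tests below were chosen after the result they bear on was seen, except the comparison of siLuc with untreated libraries along CLIP enrichment, whose prediction was written before it was computed.

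Non-coding transcripts lay on both sides in CLIP. Of 87 non-coding transcripts 54 were enriched and 17 depleted (median 1.55), and of 32 snoRNAs 28 were enriched (median 2.85, at a median of 37.5 untreated counts). A further let-7 precursor, Mirlet7d, chosen after its values were seen, had 137, 179 and 226 CLIP counts against 8 poly(A) counts, a ratio of 33.04 (16.6 to 76.9). In the authors' deposited table the median log2 ratio over the ER class was 0.49, 0.43 and 0.45 by antibody in coding sequence and 1.35, 1.33 and 1.37 in 3′ UTRs. In the authors' deposited table the free-ribosome class was at −0.90, −0.92 and −1 in coding sequence and −0.72, −0.66 and −0.56 in 3′ UTRs. The deposited ratios carry no depth factor, as checked for the exon ratios. All coding transcripts in the authors' deposited table were at −0.71, −0.71 and −0.67 in coding sequence and −0.07, −0.05 and 0.05 in 3′ UTRs. The medians of the 2 regions cover different sets of transcripts. These were 286 in coding sequence and 233 in 3′ UTRs for the ER class and 376 and 228 for the free-ribosome class. For all coding transcripts they were 6086 and 3577. Coding sequence held 67.0% ± 0.25 of CLIP exon counts of coding transcripts (SD, n = 3), in transcripts with 55.1% coding sequence by length. The first share weights transcripts by their reads and the second does not, so the 2 are not directly comparable. Relative to poly(A) RNA coding sequence was lower than the 3′ UTR, over the 3092 (35L33G), 3116 (2J3) and 3141 (polyclonal) transcripts with both ratios. In the authors' deposited table their median log2 ratio of coding sequence minus 3′ UTR was −0.29, −0.33 and −0.36 by antibody.

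CLIP enrichment and ribosome density change were correlated across transcripts (rank correlation 0.484). Transcript length, coding length and abundance do not account for it, as the rank correlation given all 3 was 0.480. Nor does the ER class alone, with 0.455 outside it. Over the lower deciles of enrichment the rise was mostly in the mRNA change. From decile 1 to decile 7 the mRNA median went from 0.25 to −0.09, while the footprint median was −0.11 and −0.07. Footprints rose in deciles 8 to 10, at 0.09, 0.24 and 0.70, and their rank correlation over all transcripts was 0.284. Part of the relation may come from the poly(A) libraries. The siLuc to untreated mRNA change had a rank correlation of 0.260 with CLIP counts over siLin28a poly(A) RNA. No library is shared in that comparison. What stays open is whether the footprint libraries differ in the same way without Lin28a siRNA, since there is 1 per condition. ER-made transcripts outside the preset lists, not analysed here, also stay open.

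Replication-dependent histones lay far above the poly(A) input. Their median exceeded that of the variant histones by 7.37 (log2), which is consistent with RNA lacking a poly(A) tail being missing from the input. The same may hold for the small RNAs, which was not tested and for which a poly(A) input gives no measure of abundance. LIN28A binding of histone mRNA remains untested.

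Unfolded protein and integrated stress response transcripts had a median of −0.47 with siLin28a against siLuc (percentile 0 of matched lists). Against untreated cells the siLin28a median was 0.15, and the siLuc library stood at 0.29 over untreated (percentile 99.9). A raised siLuc library is a candidate explanation of the difference; a Lin28a effect on these genes was not separable with 1 library per condition.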
